A study of Mus musculus with 24 samples.

How the data were processed

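RNA from wild-type and Atf4 knockout mouse embryonic cortical neurons, untreated or exposed to HCA, was read on 24 Illumina Mouse Ref-8 arrays, 1 sample per array. Groups, replicate numbers and chips were taken from the labels and never from the values. The labels do not say whether replicates are separate cultures or separate animals, so the p-values measure the spread between these samples only. The HCA dose, the length of exposure and the number of embryos per culture are not given in the sources used here.

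Per the file headers, BeadStudio 1.5.1.3 summarised the beads of each probe to an average signal, an intensity on a linear scale without normalization, and the authors deposited these values for 24048 probes. Per the file headers the same program gave each probe a detection score from 0 to 1, and the score was taken here as 1 minus a detection p, because it rose with the signal. The authors also deposited a matrix of log2 values for 23983 probes, per the labels made with limma in a version that is not given. Recomputing quantile-normalized log2 signals from the raw table gave that matrix to within 5e-14 for each of its 23983 probes.

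Of the probes, 20919 had 1 gene symbol, 1 had several and 3063 had none. Symbols were matched to the RefSeq gene table of mouse GRCm38.p6 for 20913 probes, and 7 symbols were updated. That table was used for names and gene order alone. Entrez numbers in the raw IDs equalled those of the annotation for 7932 of 7964 probes, or 99.6%. The array named 15943 genes, 3691 of them with more than 1 probe.

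The signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 (offset 16), with the mean and SD of the negative controls inferred from the detection values. The inferred SD was 214 to 302 on the arrays of chip 1 and 240 on wild-type HCA replicate 3, against 15.4 to 26.6 on the others, where detection quantiles gave 16.7 to 27.9 on all arrays. Probes detected (p under 0.05) on at least 4 arrays were kept, 11884 in all, and each gene was represented by its brightest probe. This left 8755 genes, 54.9% of those named. Limma's lmFit and eBayes were fitted to all 24 arrays with a term for each group and for chip, with 18 residual degrees of freedom and 4.73 prior ones. The 5 contrasts were knockout minus wild type without HCA, the same with HCA, HCA minus untreated in each genotype, and the difference between those responses. They share arrays, so their chance errors are shared too. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from limma. A count at an unadjusted p is of genes with limma's p under 0.05, which are not calls. If no gene differed, a share of about 0.05 of the tested genes would pass it, so a count near or below that share shows no response. Where a gene was detected on no array of a group, its fold is a lower bound against the dimmest detected probe.

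For each comparison the text names Atf4, the 10 highest and the 10 lowest called genes whose sign was the same on each chip, up to 4 members of each list by p, and 10 genes named whatever their value (Slc7a11, Chac1, Trib3, Ddit3, Asns, Atf3, Hmox1, Nqo1, Gclm and Cdkn1a). Other list members and other genes in the text were named after their values were seen. The 26 gene lists held 358 members, of which 232 were tested. They covered amino acid synthesis and transport, tRNA synthetases, stress regulators, ER chaperones, NRF2 and glutathione genes, p53 targets, immediate early genes, heat shock, hypoxia and glycolysis, cholesterol synthesis, interferon, neuron classes, progenitors, dividing cells, glia, endothelium, meninges, choroid plexus, erythroid cells and sex-linked genes. The choroid plexus list had fewer than 2 tested members and was left out, which leaves 25 lists. Each was tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and p was adjusted over 125 tests. An adjusted p of a list without further words is from the preset correlation.

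Lists, named genes, contrasts, tests and the main alternatives were fixed before the data were examined. The alternatives were another background correction, median centring, the deposited values, other detection filters, the mean of a gene's probes, other uses of chip, replicate number as a block, fewer groups in the fit, array weights and leaving out each array. Chosen after the data were seen were a background spread read from detection quantiles (with quantile normalization or median centring), array sets as a block, the Eif2s3y level as a covariate, leaving out the 2 arrays that stand apart for most probes, the test of chip by genotype, the tests of probes with a gap in level and of genes near Atf4, and splits of the arrays within chips.

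The procedure was tested on simulated data of 8755 genes, 100 of them changed by 0.5 and 100 by 1 on the log2 scale. A further list of genes was shifted by less. Noise was drawn independently for each gene and array, without array sets or a knockout difference that varies with the chip. With a log2 change of 0.5, it called 95, 86, 80, 84 and 75 of the 100 in the order of the contrasts above, and with a change of 1 it called 99, 100, 100, 100 and 96. Of the unchanged genes it called between 8 and 14. The 1222 tested probes without a gene name were fitted apart. R 4.3.3, data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.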

Results

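Expression was measured in wild-type and Atf4 knockout mouse embryonic cortical neurons, left untreated or exposed to homocysteate (HCA). ATF4 is a transcription factor of the integrated stress response, the pathway by which cells adjust translation, amino acid supply and redox defence under stress. HCA is a glutamate homolog that competes with cystine for uptake into the cell and so lowers glutathione, which makes it a source of oxidative stress. There were 8 untreated wild-type arrays, 8 untreated knockout arrays, 4 wild-type arrays with HCA and 4 knockout arrays with HCA, 24 in all, on 3 Illumina Mouse Ref-8 BeadChips of 8 arrays each. Chip 1 held 4 untreated arrays of each genotype and no HCA array, and chips 2 and 3 each held 2 arrays of each of the 4 groups. The mean raw signal per array ranged from 745 to 983 on chip 1, from 342 to 537 on chip 2 and from 296 to 669 on chip 3. Between 36.6% and 47.9% of the probes were detected on an array, and 8755 genes were tested. The number of arrays limits the precision of every value below.

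Atf4 itself was read first, as a check of the labels. Its mean log2 intensity was 9.98 ± 0.21 (SD, n = 8) in untreated wild-type neurons and 6.44 ± 0.06 (SD, n = 8) in untreated knockout neurons. With HCA it was 10.56 ± 0.22 (SD, n = 4) in wild type and 6.39 ± 0.01 (SD, n = 4) in knockout. The Atf4 probe was detected on 8 of 8 and 4 of 4 wild-type arrays and on 0 of 8 and 0 of 4 knockout arrays. Measured against the dimmest probe detected on the knockout arrays, Atf4 was at least 9.37-fold lower in knockout without treatment and at least 12.9-fold lower with HCA. Which part of the gene the probe reads, and which part was disrupted, are not given in the sources used here. HCA raised Atf4 mRNA in wild type by 0.59 ± 0.10 on the log2 scale (SE, adjusted p = 0.00136, limma).

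**Figure D1:**
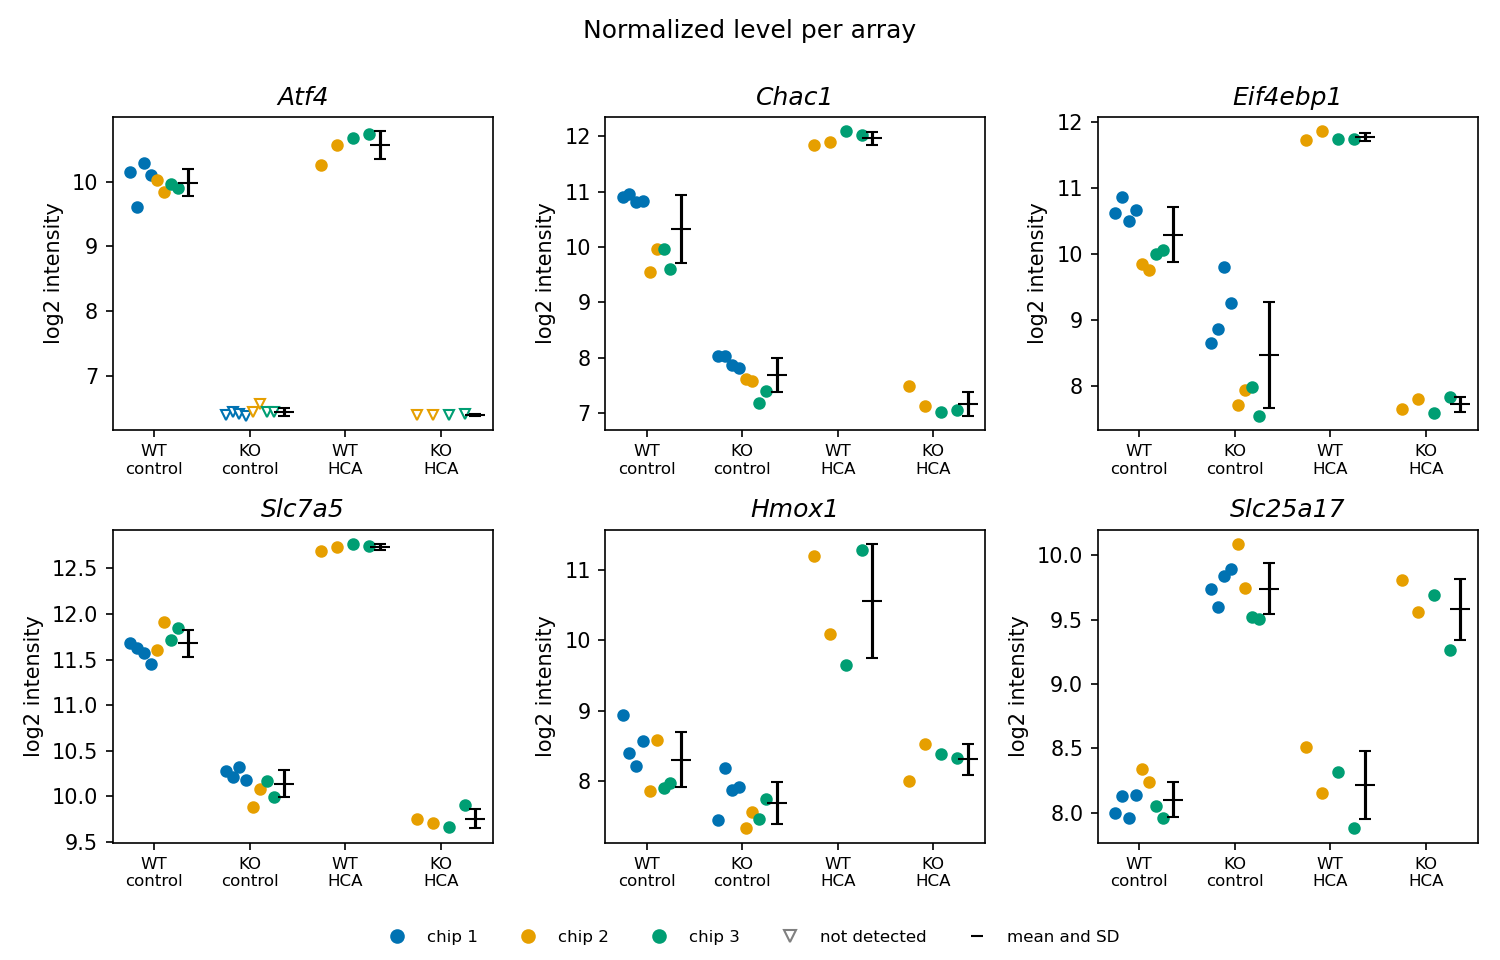
Normalized log2 intensity (vertical axis) of 6 genes on each array, by group (horizontal axis). Filled points are arrays on which the gene was detected, coloured by chip, open triangles are arrays on which it was not, and black marks give the mean and SD of each group. Atf4 lies at 6.44 in untreated and 6.39 in HCA-treated knockout arrays, and Chac1 rises from 10.32 to 11.96 with HCA in wild type and lies at 7.69 and 7.18 in knockout. Untreated arrays come from every chip and HCA arrays from chips 2 and 3 alone, so differences between these means hold chip effects. On chips 2 and 3 alone Chac1 changed by 2.19 in wild type and by -0.27 in knockout.

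The first comparison, untreated knockout against untreated wild-type neurons, asks what loss of Atf4 changes without an added stressor. The genes furthest below wild type in knockout, next to Atf4, were Chac1, an enzyme that degrades glutathione, which was 6.19-fold lower (log2 fold change -2.63 ± 0.10, SE, n = 8 per group), and Slc7a3, a transporter of cationic amino acids, which was 6.14-fold lower (-2.62 ± 0.06). Eif4ebp1, a repressor of cap-dependent translation, was 3.53-fold lower, Slc7a5, the light chain of the large neutral amino acid transporter, 2.90-fold lower, Slc6a9, a glycine transporter, 2.73-fold lower, and Atf5, a stress-induced transcription factor, 2.68-fold lower. Cox6a2, a muscle-type subunit of cytochrome c oxidase that 3 of 8 knockout arrays detected, was 3.58-fold lower and Mgat3, a glycosyltransferase of N-glycan synthesis, 3.09-fold lower. Pou6f1, a POU-domain transcription factor, was also called lower. On chip 1 it lay between 10.5 and 11.5 on the 4 wild-type arrays and between 6.42 and 10.6 on the 4 knockout arrays, of which 1 detected it. It was at the detection limit in both genotypes on chips 2 and 3, so no difference could be measured there. The highest gene in knockout was Slc25a17, a peroxisomal carrier of cofactors, 3.12-fold higher (log2 fold change 1.64 ± 0.08).

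The other genes highest in untreated knockout neurons differed by less. Rasgrp1, a Ras exchange factor, was 1.67-fold higher, Atp2c1, a Golgi calcium and manganese pump, 1.66-fold, Trmt9b 1.62-fold, the ribosomal protein gene Rpl29 1.62-fold, the adaptor Blnk 1.61-fold, the membrane glycoprotein Cd200 1.61-fold, Dbpht2 1.60-fold, the potassium channel Kcnc4 1.58-fold and Ovgp1 1.51-fold, with adjusted p from 8.69e-06 (Rasgrp1) to 0.0345 (Trmt9b). Of these genes 3 had a further probe, detected on 10 or more arrays, that did not show the difference, with log2 differences of -0.04 for Atp2c1, 0.03 for Ovgp1 and 0.02 for Rasgrp1. Among the genes fixed beforehand, asparagine synthetase (Asns) was 2.26-fold lower (adjusted p = 2.04e-09, and by a log2 difference of -0.45 on a further probe), heme oxygenase Hmox1 1.53-fold lower (adjusted p = 0.0304) and the cell cycle inhibitor Cdkn1a 1.17-fold higher (adjusted p = 0.0238). Ddit3, which encodes the stress factor CHOP, had a log2 difference of -0.20 ± 0.10 (adjusted p = 0.191), and Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, one of -0.14 ± 0.06 (adjusted p = 0.130). Slc7a11 and Trib3 were detected on 0 arrays, Atf3 on 2 and Nqo1 on 3, so these 4 genes were not tested.

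By gene list, 10 of 14 measured stress regulators of the integrated stress response were lower in untreated knockout neurons and 0 higher (10 lower adjusted over the list alone), with a median log2 difference of -0.43. Besides Chac1, Eif4ebp1 and Atf5, these included Herpud1 (-0.66), Cebpb (-0.59) and Vegfa (-0.61). Of 11 measured genes of amino acid synthesis, 8 were lower (8 adjusted over the list alone), led by Psat1 of serine synthesis (-1.25), Asns (-1.18) and the mitochondrial folate enzymes Shmt2 (-0.92) and Mthfd2 (-0.85). Of 10 amino acid transporters, 5 were lower, among them Slc3a2 (-0.72) and Slc1a4 (-0.48) beside Slc7a3, Slc7a5 and Slc6a9, and 1, Slc7a6, was higher (0.18). Of 14 cytosolic tRNA synthetases, 5 were lower, namely Cars (-1.18), Aars (-0.64), Nars (-0.61), Sars (-0.30) and Gars (-0.17), and 6 adjusted over the list alone. These 4 lists held in limma's camera test both with a preset correlation between genes and with an estimated one, where adjusted p was 1.52e-05, 4.06e-05, 0.000108 and 0.0278. On chips 2 and 3 alone the tRNA synthetases missed the threshold with an estimated correlation (adjusted p = 0.0708).

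Genes of dividing cells and of sterol synthesis were lower too. Of 15 measured cell division genes, 12 were lower in untreated knockout neurons, among them the spindle and chromosome genes Top2a (-0.79), Cdc20 (-0.79) and Cdk1 (-0.73), but the list's adjusted p rose from 7.72e-11 to 0.107 with an estimated correlation. Of 14 cholesterol synthesis genes, 12 were lower, led by Stard4 (-0.82), Mvd (-0.74) and Lss (-0.63), with adjusted p = 0.133 with an estimated correlation. Of 11 genes of ER chaperones and ER-associated degradation, 7 were lower, among them Hsp90b1 (-0.53) and Pdia4 (-0.49), with adjusted p = 0.178 with an estimated correlation. Markers of other cell types moved in the same direction in these samples. Of 10 genes of neural progenitors and radial glia, 5 were lower, with Hes5 (-1.06) and Sox2 (-0.76) first, and of 7 astrocyte genes, 4 were lower, with Aqp4 (-0.91) and Aldh1l1 (-0.56) first. Microglia and macrophage genes were lower in 6 of 9 and inhibitory neuron genes in 5 of 8, Npy (-0.60) and Calb2 (-0.41) first. With an estimated correlation these 4 lists had adjusted p = 0.0965, 0.236, 0.135 and 0.0965. Pan-neuronal and synaptic genes had a median log2 difference of 0.01 (adjusted p = 0.452), with 1 of 11 called, neurofilament Nefm (0.58), and 3 of 7 genes of excitatory cortical neurons were higher, Fezf2 (0.56), Slc17a6 (0.33) and Neurod2 (0.26), with adjusted p = 0.0858 for the list. Glutathione genes were lower in 5 of 12, Gsta4 (-0.69) and Gstm1 (-0.56) first, and NRF2 antioxidant genes in 3 of 14, Hmox1 (-0.62) first, with adjusted p = 0.0835 and 0.178 with an estimated correlation.

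The remaining lists did not pass in untreated neurons. Immediate early genes had 2 higher, Homer1 (0.27) and Fosb (0.19), and 1 lower, Egr1 (-0.78), of 13 (adjusted p = 0.302), and the call of Fosb was lost in 27 of 43 alternatives. Heat shock proteins had 2 of 10 lower, Bag3 (-0.44) and Hsph1 (-0.27), with adjusted p = 0.246, and hypoxia and glycolysis had Pfkfb3 (0.36) higher and Egln3 (-0.33) and Pgk1 (-0.20) lower of 13, with adjusted p = 0.233. Genes of the oligodendrocyte lineage were lower in 2 of 5, Olig1 (-0.89) and Pdgfra (-0.19, lost in 29 of 43 alternatives), and those of meninges and fibroblasts in 2 of 5, Col1a1 (-0.47) and Col6a1 (-0.39), with adjusted p = 0.0547 and 0.113. The lists of p53 targets (1 of 8 called), interferon response (1 of 2), endothelium and pericytes (0 of 4), erythroid cells (0 of 2) and sex-linked genes (0 of 2) had adjusted p = 0.515, 0.149, 0.391, 0.697 and 0.575.

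Over all genes, 1278 of 8755 differed between untreated knockout and wild type at the set false discovery rate, 632 higher and 646 lower in knockout (limma). Of the higher genes 11 and of the lower genes 99 differed by 1.5-fold or more, and 1220 of the 1278 had the same sign on each of the 3 chips. On chip 1 alone 31 genes passed, against 421 on chip 2 and 753 on chip 3, and without a chip term 305 passed. With median centring in place of quantile normalization 16 genes passed, 1 higher and 15 lower, and the median of all genes moved to 0.09. With a background spread read from detection quantiles 1092 passed, and 154 with median centring as well.

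**Figure D2:**
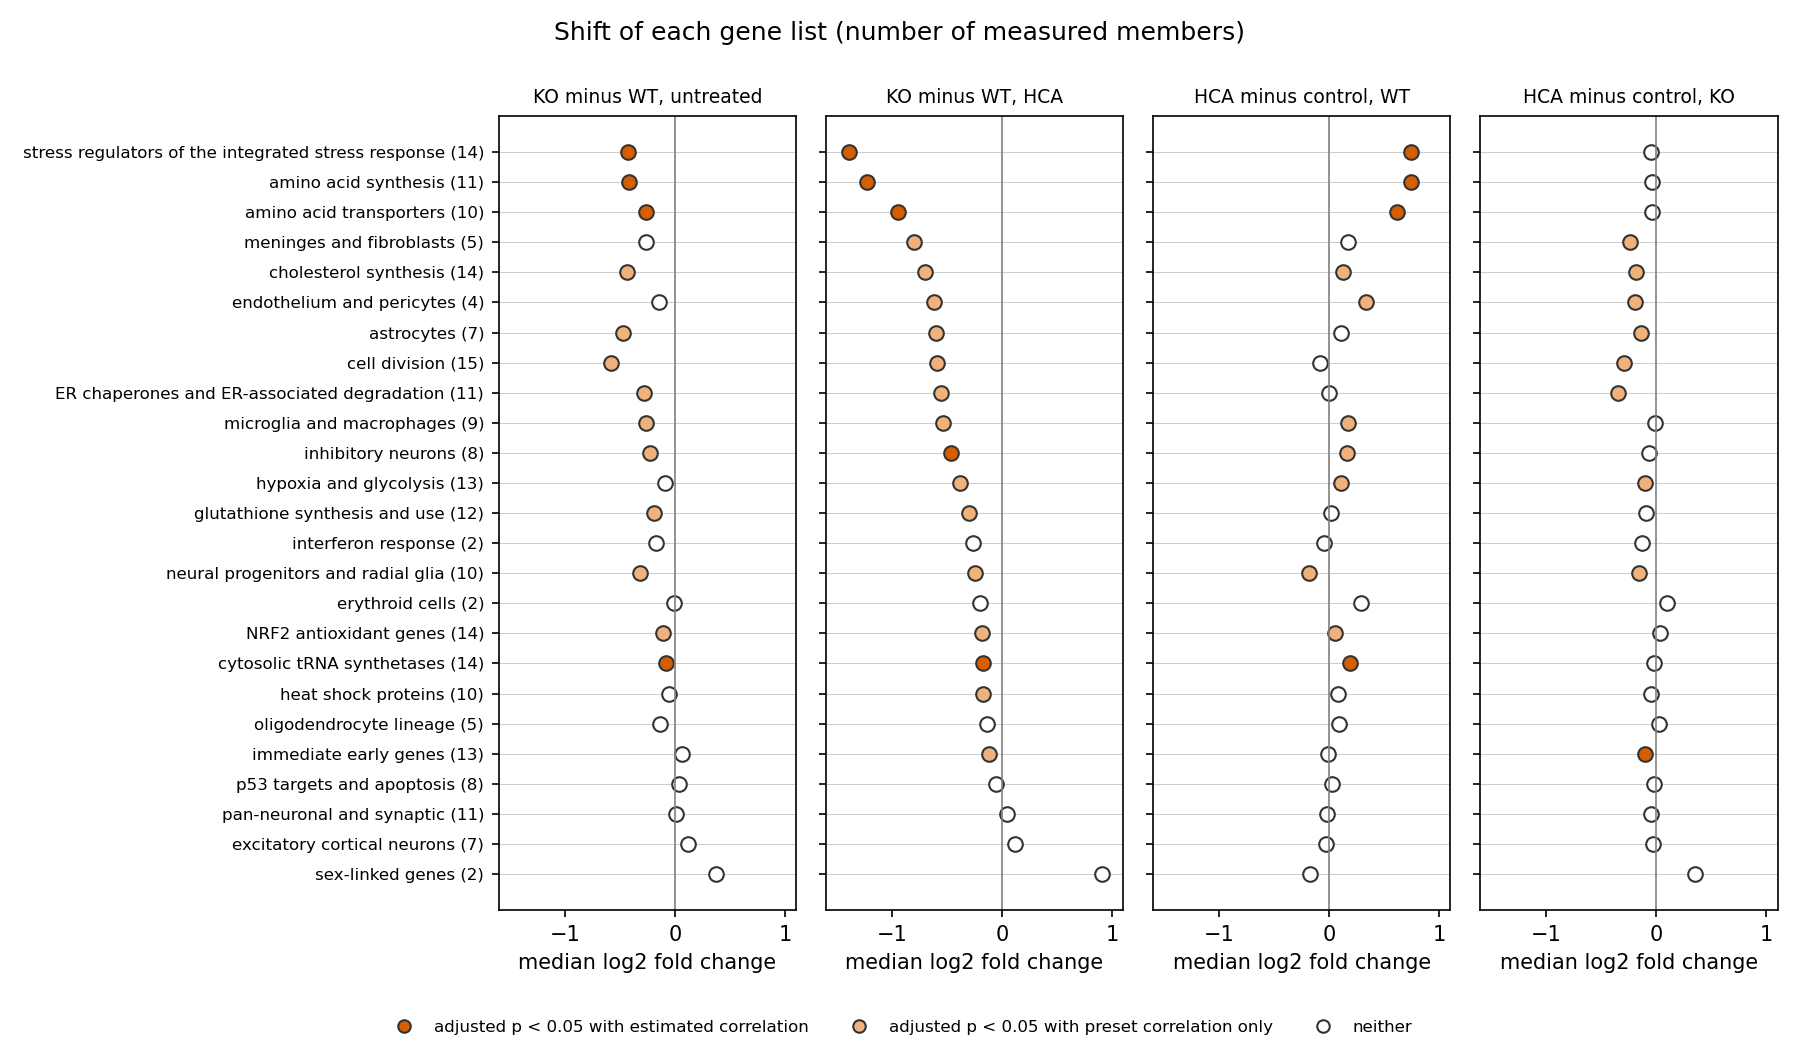
Median log2 fold change (horizontal axis) of each gene list (vertical axis, with its number of measured members) in 4 comparisons. Filled points passed the camera test with an estimated correlation, pale points with the preset correlation only. The 14 stress regulators shift to -0.43 in untreated knockout, to -1.39 in knockout with HCA and to 0.74 with HCA in wild type.

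The same contrast under HCA, knockout against wild type, asks how the genotypes differ during oxidative stress. Chac1 was 27.6-fold lower in knockout (log2 fold change -4.79 ± 0.14, SE, n = 4 per group), Eif4ebp1 16.6-fold lower (-4.05 ± 0.18), Slc7a3 12.7-fold lower, Slc7a5 7.87-fold lower and Slc6a9 7.73-fold lower. Cars, the cysteinyl-tRNA synthetase, was 7.00-fold lower, Psat1 6.75-fold lower, Mgp, an inhibitor of matrix calcification, 6.27-fold lower, and Nupr1, a stress-induced chromatin protein, at least 4.49-fold lower, its knockout arrays lying at the detection limit. Of the genes fixed beforehand, Asns was 4.81-fold lower (-1.45 on the log2 scale on a further probe), Hmox1 4.72-fold lower and Ddit3 1.71-fold lower. Cdkn1a was 1.38-fold lower, and Gclm had a log2 difference of -0.20 ± 0.09 (adjusted p = 0.115). Higher in knockout were Slc25a17 (2.58-fold), the autophagy enzyme Atg3 (2.47-fold), Rpl29 (2.23-fold), Cdk5rap1 (2.13-fold), Kcnc4 (2.06-fold), the transcription factor of deep-layer cortical neurons Fezf2 (2.05-fold), Lrrc40 (2.03-fold), the adrenergic receptor Adra2c (2.02-fold), Cd200 (1.95-fold) and Igsf21 (1.93-fold), with adjusted p from 4.31e-09 (Slc25a17) to 0.00664 (Atg3). Further probes of Cdk5rap1 had log2 differences of 0.86 and 0.30.

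All 14 measured stress regulators were lower in HCA-treated knockout neurons (14 adjusted over the list alone), with a median log2 difference of -1.39, and so were 8 of 11 genes of amino acid synthesis (median -1.23), 7 of 10 amino acid transporters (median -0.94) and 7 of 14 tRNA synthetases (median -0.17). Examples were Atf5 (-2.11), Vegfa (-1.98), Mthfd2 (-2.42), Shmt2 (-1.80), Slc3a2 (-1.58), Nars (-1.31) and Aars (-1.26). With an estimated correlation these 4 lists had adjusted p = 2.37e-07, 1.45e-05, 4.58e-06 and 0.00280. Inhibitory neuron genes were lower in 5 of 8, Npy (-0.84), Dlx1 (-0.53) and Slc32a1 (-0.52) first, with adjusted p = 0.0386 with an estimated correlation. Cholesterol synthesis genes were lower in 13 of 14, cell division genes in 11 of 15, ER chaperone genes in 7 of 11 and genes of hypoxia and glycolysis in 7 of 13, hexokinase Hk2 (-1.12) and Ldha (-0.54) among them. Their adjusted p with an estimated correlation was 0.106, 0.184, 0.178 and 0.0850. Fitted on chips 2 and 3 alone, which hold all HCA arrays, these 4 lists passed with it (adjusted p = 0.0056, 0.012, 0.0108 and 0.0409). Immediate early genes were lower in 5 of 13, including Egr1 (-1.30) and Jun (-0.73), with 1 higher, Homer1 (0.45), and adjusted p = 0.199 with an estimated correlation. Glutathione genes were lower in 5 of 12, Gsta4 (-1.18) and Gstm1 (-0.93) first (adjusted p = 0.0945 with an estimated correlation). On chips 2 and 3 alone 7 of 12 were lower and the list passed (adjusted p = 0.00484 with an estimated correlation). The list of NRF2 antioxidant genes had 2 of 14 called, Hmox1 and Prdx1 (-0.67), with adjusted p = 0.150 with an estimated correlation. Markers of other cells were lower here as well, in 7 of 9 microglia genes, 4 of 7 astrocyte genes, 3 of 5 genes of meninges and fibroblasts and 3 of 4 of endothelium and pericytes, Aqp4 (-1.32), Igf2 (-1.10) and Pdgfrb (-0.78) among them. Their adjusted p with an estimated correlation was 0.110, 0.199, 0.0965 and 0.232. Fitted on chips 2 and 3 alone it was 0.0129, 0.151, 0.012 and 0.131, so microglia and meninges and fibroblasts passed there. Neurofilament Nefm was higher (0.78), and Tubb3 was lower (-0.44).

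In total 1912 genes differed, 1012 higher and 900 lower in knockout, of which 80 and 295 by 1.5-fold or more, and 1912 had the same sign on both chips that held HCA arrays. With median centring 67 genes passed, with the median of all genes at 0.36, or 412 with the background spread read from detection quantiles, and without a chip term 848. The genotypes were not balanced for the Y-linked gene Eif2s3y here. It lay between 8.67 and 9.88 on the knockout arrays with HCA. On wild-type HCA replicates 1 and 4 it lay at 10.1 and 8.75, and on replicates 2 and 3 at 6.42 and 6.5.

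HCA against untreated in wild-type neurons asks which genes respond to the stressor. Chip 1 holds no HCA array, so its untreated arrays entered the HCA responses of both genotypes through the chip term. The fit thereby took the knockout difference as equal on each chip, which failed for 530 genes in a test given below. Both responses over all arrays, and the difference between them, rest in part on this, so some values on chips 2 and 3 alone are given as well. Hmox1, which degrades heme, rose 5.43-fold (log2 fold change 2.44 ± 0.25, SE, n = 4 against 8), Chac1 4.11-fold (2.04 ± 0.13), Eif4ebp1 4.00-fold (2.00 ± 0.17) and Nupr1 3.54-fold (1.82 ± 0.14). Mthfd2 rose 2.84-fold, Slc6a9 2.66-fold, the mTOR inhibitor Ddit4 2.6-fold, Cars 2.55-fold, the early response gene Ier3 2.44-fold and the angiogenic factor Vegfa 2.33-fold. The genes that fell most were Cyp26b1, an enzyme that clears retinoic acid, 1.88-fold, Sv2b of synaptic vesicles, 1.64-fold, Fezf2, 1.57-fold, Aard, 1.55-fold, and Wscd1, 1.48-fold. Lnx2, the phosphomannomutase Pmm1, Adra2c, Scrn1 and Rgs7, a regulator of G-protein signalling, fell between 1.41-fold (Rgs7) and 1.42-fold (Lnx2). A further probe of Scrn1, detected on 11 arrays, had a log2 difference of -0.15. Asns rose 1.75-fold, Cdkn1a 1.45-fold and Ddit3 1.43-fold (adjusted p = 0.0459). The call of Ddit3 was lost in 27 of 43 alternatives and that of Fezf2 in 16 of 43. Gclm had a log2 difference of 0.18 ± 0.08 (adjusted p = 0.316).

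All 14 measured stress regulators rose with HCA in wild type (14 adjusted over the list alone), Ddit3 not in 27 of 43 alternatives, with a median log2 change of 0.74. Of the genes of amino acid synthesis 7 of 11 rose (median 0.74), with Mthfd2 (1.51), Psat1 (0.91), Shmt2 (0.91) and Gpt2 (0.85) first, and of the amino acid transporters 7 of 10 (median 0.61), with Slc6a9 (1.41), Slc7a3 (1.15) and Slc7a5 (1.06) first. Of the tRNA synthetases 6 of 14 rose, with Cars (1.35), Tars (0.66) and Aars (0.55) first, and their list median of 0.19 became -0.13 with median centring, where the median of all genes moved to -0.39. With an estimated correlation the 4 lists had adjusted p = 5.97e-08, 7.31e-06, 1.67e-07 and 0.00165. The NRF2 list had 1 of 14 called, Hmox1, and adjusted p = 0.158 with an estimated correlation, and the glutathione list had 0 of 12 called (adjusted p = 0.355). Of 13 genes of hypoxia and glycolysis 2 rose, Hk2 (0.70) and the collagen hydroxylase P4ha1 (0.53), with adjusted p = 0.139 with an estimated correlation. Of 13 immediate early genes 1 rose, Jun (0.78), and adjusted p of the list was 0.182. The ER chaperone list had 0 of 11 called (adjusted p = 0.887), heat shock proteins 0 of 10 (adjusted p = 0.196) and the list of p53 targets and apoptosis 1 of 8, Cdkn1a (adjusted p = 0.159).

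In all, 146 genes responded to HCA in wild type, 92 up and 54 down, 32 and 4 of them by 1.5-fold or more (limma). On chips 2 and 3 alone, where each HCA array has untreated arrays beside it, 254 genes passed, 110 up and 144 down, and 120 of the 146 were among them with the same sign. Without wild-type HCA replicate 1 the count was 74, and with median centring it was 2, or 18 with the background spread read from detection quantiles. The HCA dose and the time of exposure are not given in the sources used here.

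HCA against untreated in knockout neurons asks whether the response remains without Atf4. Of the stress regulators 0 of 14 passed, with a median log2 change of -0.05, against a median of 0.74 in wild type. Chac1 had a log2 difference of -0.12 ± 0.13 (SE, n = 4 against 8, adjusted p = 0.858), Asns of -0.29 ± 0.12 (adjusted p = 0.520), Ddit3 of -0.05 ± 0.13 (adjusted p = 0.949) and Cdkn1a of -0.15 ± 0.09 (adjusted p = 0.650). Hmox1 had a log2 difference of 0.82 ± 0.25 that missed the threshold (adjusted p = 0.361), and Gclm one of 0.13 ± 0.08 (adjusted p = 0.704). The 5 genes that passed all fell. These were the metal-binding protein Mt1 (-0.74 ± 0.12), the plasminogen activator Plat (-0.48 ± 0.08), the activity-dependent transcription factor Fosb (at least 1.1-fold, its HCA arrays lying at the detection limit), the exchange factor Rasgrf1 (-0.44 ± 0.08) and the adhesion receptor Adgra1 (-0.42 ± 0.07), with adjusted p from 0.0148 (Mt1) to 0.0412 (Fosb). Immediate early genes shifted down as a list, with 1 of 13 called, 12 of 13 negative and adjusted p = 0.0318 with an estimated correlation. Fos had a log2 difference of -0.55 (adjusted p = 0.197) and Egr1 one of -0.35 (adjusted p = 0.721). At an unadjusted p, 737 genes passed. The count of 5 depended on single arrays, falling to 0 without knockout HCA replicate 3, knockout HCA replicate 4 or knockout control replicate 7, and 3 of 36 splits of the knockout arrays within chips, the real one included, gave as many genes. The calls of Rasgrf1 and Fosb were lost in 31 and 22 alternatives and kept in 12 and 20, and that of Adgra1 was lost in 13 and kept in 29. On chips 2 and 3 alone 6 genes passed, 3 of the 5 among them, Mt1, Plat and Fosb, and Emp1 (-0.98), a membrane protein named after its values were seen.

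**Figure D3:**
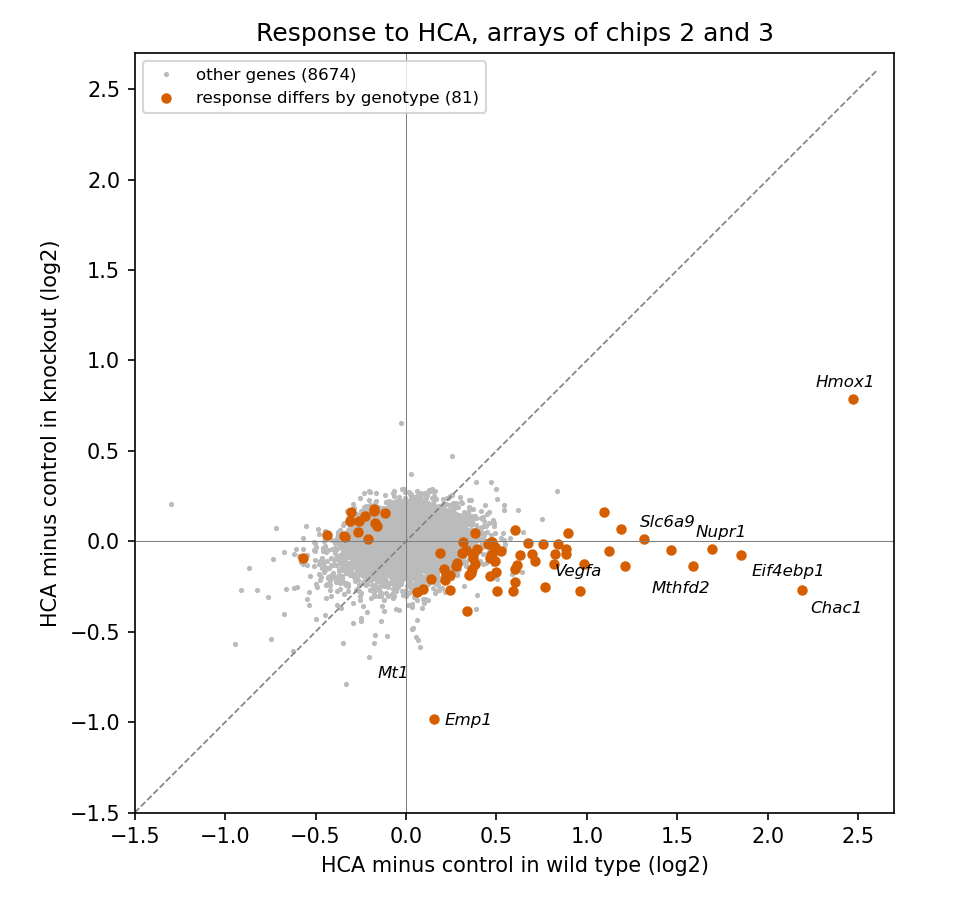
Log2 change with HCA on the 16 arrays of chips 2 and 3 in wild type (horizontal axis) and knockout (vertical axis), 1 point per gene. Orange points are the 81 genes whose response differed by genotype over all arrays, and the dashed line marks equal responses. Chac1 lies at 2.19 in wild type and -0.27 in knockout, Eif4ebp1 at 1.85 and -0.08, and Hmox1 at 2.47 and 0.79.

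The difference between the responses was then tested directly. It was largest for Eif4ebp1 (log2 response in knockout minus wild type -2.23 ± 0.22, SE), Chac1 (-2.16 ± 0.17), Cars (-1.63 ± 0.36), Hmox1 (-1.63 ± 0.33), Mthfd2 (-1.57 ± 0.11), Psat1 (-1.51 ± 0.26), Slc6a9 (-1.499 ± 0.16), Slc7a5 (-1.44 ± 0.12) and Vegfa (-1.37 ± 0.18). Nupr1 passed as well, but 1 of 8 untreated and 0 of 4 HCA-treated knockout arrays detected it, so the size of its response in knockout could not be measured. Asns (-1.09) and Cdkn1a (-0.70) passed too, Ddit3 had a difference of -0.57 ± 0.18 (adjusted p = 0.167) and Gclm one of -0.05 ± 0.11 (adjusted p = 0.889). Higher responses in knockout were found for Adra2c (0.61), the demethylase-related Alkbh7 (0.56), the replication factor Orc5 (0.55), Pithd1 (0.52), Wscd1 (0.46), Aatf (0.45), the RNA polymerase I subunit Polr1e (0.44), the splicing factor Srsf3 (0.44), the Notch effector Hey1 (0.43) and Smn1 (0.40), with adjusted p from 0.0115 (Hey1) to 0.0457 (Alkbh7). The calls of Alkbh7, Orc5, Wscd1, Aatf and Smn1 were lost in 31, 31, 31, 32 and 26 of 43 alternatives. That of Cars was lost in 13, and its probe parted the knockout arrays of chips 2 and 3 into a lower and a higher set (means 7.73 and 8.45). Of the stress regulators 11 of 14 responded less in knockout (14 adjusted over the list alone), of the amino acid synthesis genes 7 of 11, of the amino acid transporters 7 of 10 and of the tRNA synthetases 5 of 14, with adjusted p = 6.33e-08, 1.10e-05, 2.83e-07 and 0.00251 with an estimated correlation. Immediate early genes, with Jun (-0.86) and Dusp1 (-0.48) called, and genes of hypoxia and glycolysis, with Hk2 (-1.03) called, also shifted down (adjusted p = 0.0380 and 0.0386 with an estimated correlation), the latter not on chips 2 and 3 alone (adjusted p = 0.0634). In all, 81 genes differed in response, 15 higher and 66 lower in knockout (limma). On chips 2 and 3 alone 42 genes passed, 33 of them among the 81. There the difference held for Eif4ebp1, Chac1, Cars and Mthfd2, shrank to -0.86 for Psat1, and missed the threshold for Hmox1 (adjusted p = 0.0869), Cdkn1a (adjusted p = 0.0720) and each of the 10 genes named above as higher, Srsf3 nearest with adjusted p = 0.0886.

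Because chip 1 holds no HCA array, its untreated arrays and the HCA arrays of the other chips give independent sets of genes. Of the 25 genes other than Atf4 that were lower in knockout on chip 1, 15 rose with HCA in wild-type neurons on chips 2 and 3. If genes varied independently 0.314 would be shared, but genes of the same list can move together. The 25 genes had a median log2 response of 0.47 in wild type and -0.02 in knockout, where 0 of 25 passed. The 15 included Slc7a3, Slc7a5, Atf5, Asns, Mthfd2, Shmt2, Slc3a2, Slc1a4, Aars, Nars, Jdp2 and Sun2. Of the 5 genes higher in knockout on chip 1, 0 rose with HCA in wild type.

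The difference between untreated knockout and wild-type neurons itself varied with the chip. Cell division genes had a median log2 difference of -0.09 on chip 1 and -0.97 on chips 2 and 3, cholesterol synthesis genes of -0.01 and -0.78, ER chaperone genes of 0.00 and -0.53, and genes of meninges and fibroblasts of -0.03 and -0.64. The stress regulators had medians of -0.42 and -0.36 and the genes of amino acid synthesis -0.41 and -0.40. A test of this chip difference, added after the data were seen, passed with an estimated correlation for cell division (adjusted p = 0.0211), cholesterol synthesis (0.000410), ER chaperones (0.000410), glutathione (0.0353) and meninges and fibroblasts (0.0211), and gave 0.846 for the stress regulators and 0.330 for amino acid synthesis. By gene, 530 differed, 334 more negative and 196 more positive on chips 2 and 3. The fit over all arrays has no term for this, which bears on its HCA responses and on the difference between them. The cultures also differed in Eif2s3y, a Y-linked gene, which lay between 6.46 and 6.5 on the 4 knockout arrays of chip 1, between 8.67 and 9.88 on the 8 knockout arrays of chips 2 and 3, and between 6.42 and 10.1 on the 12 wild-type arrays.

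**Figure D4:**
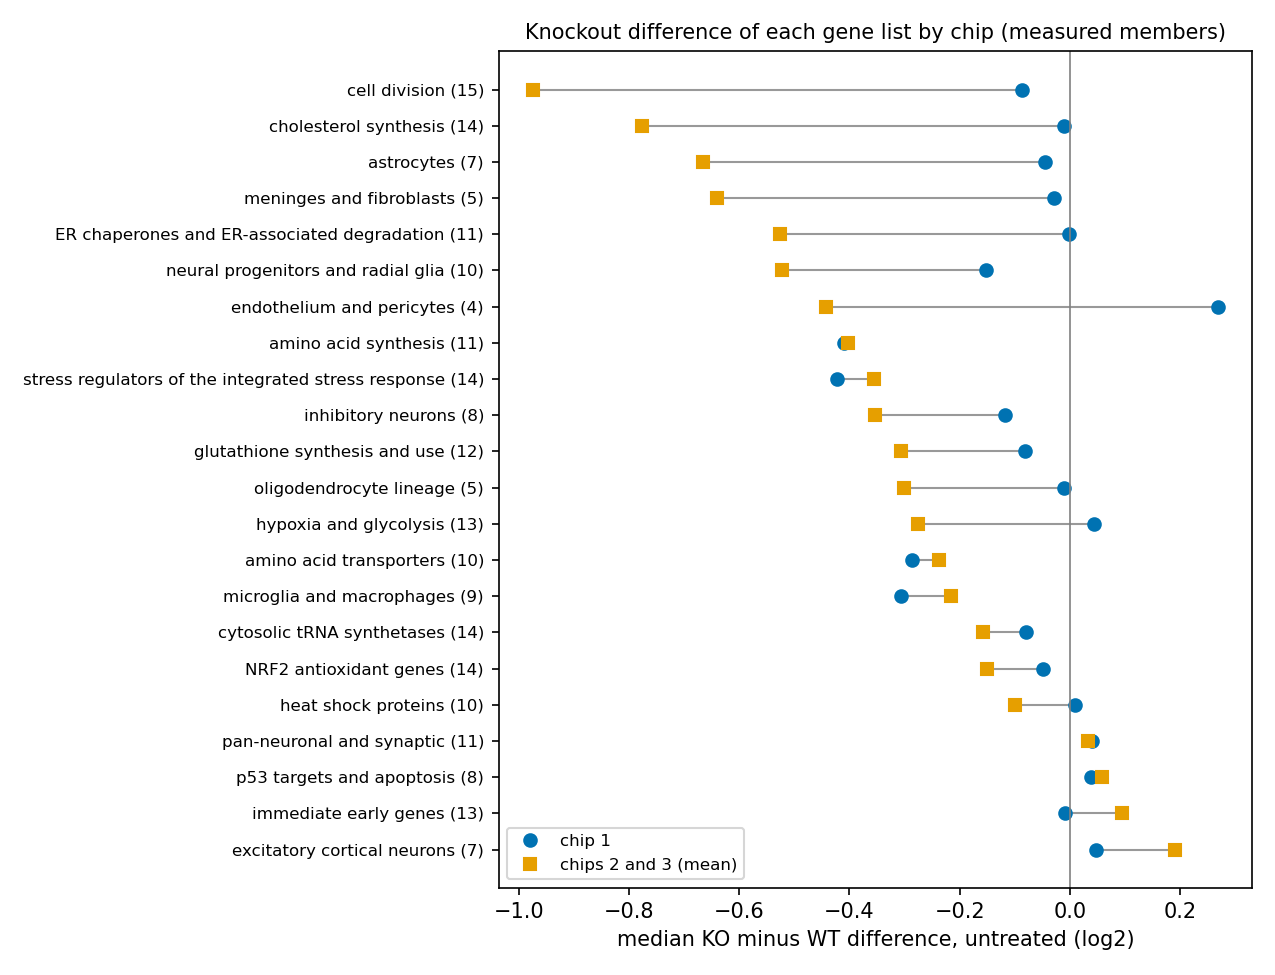
Median log2 difference between untreated knockout and wild-type neurons (horizontal axis) of each gene list with 4 or more measured members (vertical axis), on chip 1 (circles, n = 4 per genotype) and as the mean of chips 2 and 3 (squares, n = 4 per genotype). Stress regulators lie at -0.42 and -0.36, cell division genes at -0.09 and -0.97.

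A group of genes, singled out after their values were seen, parted the arrays of a genotype into a higher and a lower set. The parting followed neither genotype nor treatment, but in wild type on chips 2 and 3 it followed Y-linked genes. On the 16 arrays of chips 2 and 3, Tesk1, a protein kinase, had a mean log2 intensity of 7.05 on 4 wild-type arrays, control replicates 5 and 8 and HCA replicates 1 and 4, and of 10.75 on the other 4. Rusc2 had means of 9.69 and 12.05 over the same arrays, and Necap2, an endocytosis gene, of 10.26 and 7.70. Eif2s3y lay between 8.57 and 10.1 on the first of these wild-type sets and between 6.42 and 6.5 on the second, and the Y-linked Kdm5d between 7.1 and 7.95 and between 6.36 and 6.44. The first set lay within the first 4 places of chip 2 and the last 4 of chip 3. In knockout the arrays with the same replicate numbers parted for Arl3, a small GTPase of cilia (11.69 and 8.72), B3galt6, a glycosyltransferase (6.71 and 8.44), and Myh7, a myosin heavy chain (7.86 and 9.29), while Eif2s3y lay high in both knockout sets, between 8.67 and 9.88 and between 8.98 and 9.64. There were 14 such probes in wild type and 20 in knockout, 31 different ones, from 25 named genes. Zfp933 was found in both genotypes, in opposite directions, with means of 7.54 and 6.64 in wild type and 6.69 and 7.61 in knockout. On chip 1 the knockout arrays stood apart for Psmd8, Pop4, Nudt19 and Sbsn, which lie within 57 tested genes of each other on chromosome 7 and differed from wild type by -2.73, -1.85, -1.17 and -1.16 there and by 0.40, 0.01, 0.05 and 0.63 on chips 2 and 3.

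**Figure D5:**
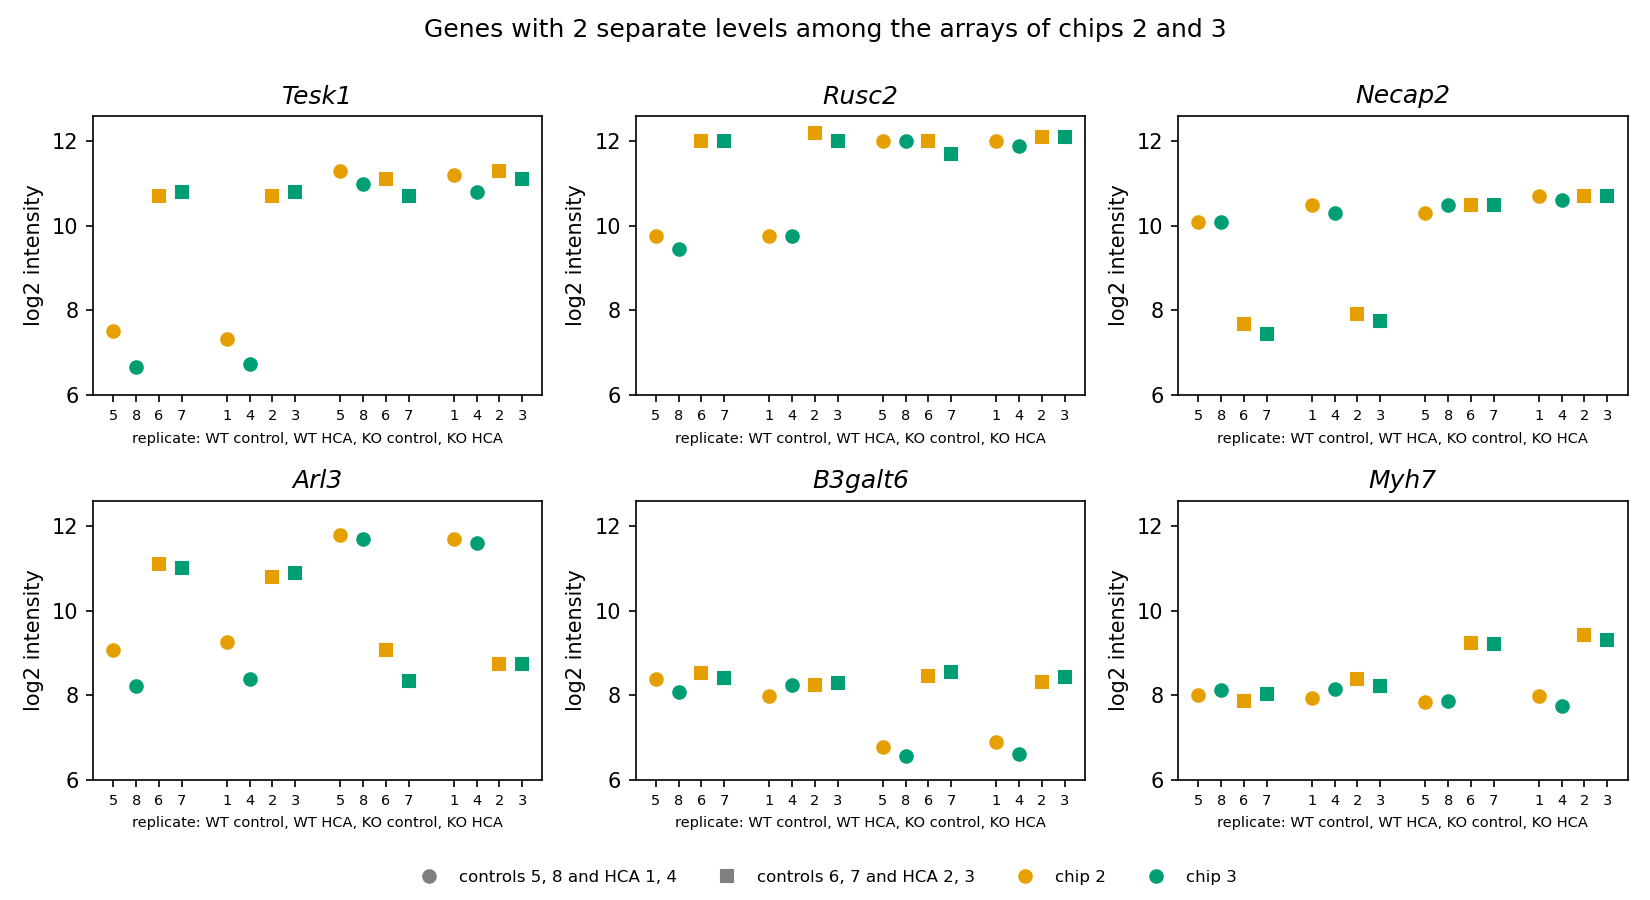
Normalized log2 intensity (vertical axis) of 6 genes on the arrays of chips 2 and 3, by genotype and array set (horizontal axis). Tesk1, Rusc2 and Necap2 part the wild-type arrays, and Arl3, B3galt6 and Myh7 the knockout arrays, into the same sets of replicate numbers.

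Genes that lie near Atf4 on its chromosome, looked at after their values were seen, were among those that differed most. Of the 5 tested genes on each side of Atf4, 4 of 10 differed between untreated knockout and wild type. Mgat3 differed by -1.63, Rps19bp1 by -1.40 (adjusted p = 1.16e-08, limma) and Slc25a17 by 1.64, and under HCA Rps19bp1 differed by -0.83 and Slc25a17 by 1.37. Sun2, a nuclear envelope protein gene 8 places away, differed by -0.79 without and -0.83 with HCA. Of the 100 tested genes on each side, 39 of 200 differed without treatment, 20 higher and 19 lower, which is 19.5% against 14.5% of the genes elsewhere (odds ratio 1.43, p = 0.0536, Fisher's exact test). Of these 39, 1 responded to HCA in wild type over all arrays, Pmm1, which fell (-0.51), and on chips 2 and 3 alone 3 did, Pmm1, Creld2 and Sun2, of which Sun2 rose (0.34, adjusted p = 0.0266).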

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

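The tests of the probes with a gap in level, of compressed fold changes, of the background spread, of the share of other cells and of the share of called genes near Atf4, the comparison of Atf4 neighbours with genes of like size, the splits within chips and the comparison of the sets between genotypes were chosen after the result was seen.

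Among 248 group values, of 60 genes, the mean signal and the percent of probes detected, 23 held an array far from the rest of its group, where chance gives about 1 in 20, or 12.4. In untreated wild type these were Atp2c1 (6.527), Rpl29 (6.866) and Atg3 (6.507) on replicate 1, Cars (7.038) and Ddit4 (8.812) on replicate 2 and Cyp26b1 (11.12) on replicate 6. In untreated knockout they were Pou6f1 (10.58), Fezf2 (12.79) and Lrrc40 (6.695) on replicate 1, Cox6a2 (7.167) on replicate 2, Atf4 (6.562) on replicate 6 and Fosb (6.668) on replicate 8. In wild type with HCA they were Rasgrp1 (7.881), Ovgp1 (9.867) and Alkbh7 (8.844) on replicate 1, Eif4ebp1 (11.86) on replicate 2, the mean signal (536.5) on replicate 3 and Slc6a9 (10.99) on replicate 4. In knockout with HCA they were Aard (7.3) on replicate 3 and Atf4 (6.413), Pou6f1 (6.356), Fezf2 (11.97) and Sv2b (7.502) on replicate 4. Knockout Atf4 values and Pou6f1 with HCA lie at the detection limit, so their distances are small. Over all tested probes, wild-type control replicate 2 and knockout control replicate 4 stood apart from the other 7 arrays of chip 1 for 82 and 33 probes, and wild-type HCA replicate 1 stood apart from the other 7 wild-type arrays of chips 2 and 3 for 73.

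The response to HCA differed between genotypes for 81 genes by a test of the difference. The differences, knockout minus wild type, were -2.23 for Eif4ebp1, -2.155 for Chac1, -1.625 for Cars, -1.625 for Hmox1, -1.568 for Mthfd2, -1.499 for Slc6a9, -1.368 for Vegfa, -1.089 for Asns and -0.6956 for Cdkn1a. For Adra2c it was 0.6091 and for Wscd1 0.4597. The fit gave -0.6209 for Atf4 and -1.998 for Nupr1, but no knockout array with HCA detected either gene, so these are no measured responses in knockout. Of the probes with no gene name, which the comparisons do not use, 154 of 1222 differed between untreated knockout and wild type, 84 higher and 70 lower.

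Other splits of the same arrays were fitted to see whether chance can be excluded. For untreated knockout against wild type, 1 of 100 splits, the real one, gave as many genes as the real 1278, and the highest other gave 1. With HCA, 1 of 35 gave as many as the real 1912, and the highest other gave 2. For HCA in knockout, 1 of 100 gave as many as the real 5, and the highest other gave 2. For HCA in wild type, 2 of 100 gave as many as the real 146, and the highest other gave 213. That split calls the 4 untreated wild-type arrays of chips 2 and 3 treated, so on these chips it parts the arrays as the real one does with the names exchanged. For the difference between responses, 2 of 100 gave as many as the real 81, and the highest other gave 505, several times the real count. That split calls the 4 knockout arrays of chip 1 treated and so points to a structure of the samples, the chip. Within chips 2 and 3 the count was 42.

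Those splits mix the chips, so labels were also exchanged within chips alone. Chance was left open where a parting other than the real one gave as many genes and the share was 0.05 or more, a rule set and once revised after the counts were seen. For untreated knockout against wild type, 1 of 100 gave as many genes as the real 1278, and the highest others gave 590 and 571. The split with 590 parts the 8 untreated arrays of chips 2 and 3 as the real one does, with the names exchanged. It differs from the real parting on chip 1 alone. With HCA the 18 such splits are too few for a share under 0.05, and the highest other gave 2 against the real 1912. For HCA in wild type, 2 of 36 gave as many as the real 146, the other being the full exchange of names with 213 genes, which parts the same arrays, and the highest other parting gave 23. For the difference between responses, 4 of 100 gave as many as the real 81, and the highest other gave 159. For HCA in knockout, 3 of 36 gave as many as the real 5, and the highest other gave 22. By both kinds of splits chance can be excluded for the untreated comparison, with the arrays taken as independent. For the difference between responses it stays open, although the rule would exclude it. There 3 of the 4 splits within chips were other partings, and 4 of 100 drawn splits lie near a bound revised after the counts were seen. For knockout against wild type with HCA chance can be excluded by the splits that mix chips 2 and 3. For HCA in wild type the splits that mix the chips also call untreated arrays of chip 1 treated, so they cannot decide alone. Within chips, 2 of 36 splits part the arrays as the real one does, which allows no share under 0.05, so chance stays open there. In both, no other parting within chips gave as many genes. All these splits exchange arrays, so they cannot exclude chance between cultures if the arrays of a set share a source. For HCA in wild type, 15 of 25 genes picked on chip 1 also rose, against 0.314 expected. That expectation takes genes as independent, but several of these genes share a gene list and can move together. The overlap therefore does not decide chance. Chance cannot be excluded for HCA in knockout, where the count also fell to 0 without any of 3 single arrays.

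The first pattern is the probes with a gap in level that part the arrays of chips 2 and 3 into the same sets in both genotypes. In all, 31 different probes followed this split, 3 of them in both genotypes, and the highest of the other splits of 4 arrays against 4, apart from treatment and chip, had 0. The sets are runs of 4 places, the first places of chip 2 with the last of chip 3 and the reverse. That 0 probes followed the same places on both chips therefore decides nothing, and the place on the chip stays open. An effect of the chip part on both genotypes alike is argued against for the probes as a group. The genotypes share these places, so such an effect needs about the same difference between sets in both. The difference in the other genotype over that in the genotype a probe was found in had a median of -0.00717 (SD 0.645), not about 1. Single probes varied. This ratio was 0.944 for Ankrd61, 0.892 for Hmgxb3 and 1.11 and 0.9 for 1 unnamed probe, but -1.1 for Gnb4 and -1.28 for Fbxo44. In knockout the sex of the cultures as what parts the sets is argued against, because the Eif2s3y levels of the sets overlap (gap -0.906). In wild type sex follows the split on chips 2 and 3, with a gap of 2.07 in Eif2s3y. For the probes as a group it stays open, since sex and any other difference between the cultures cannot be told apart there. On chip 1, wild-type control replicates 1 and 3 were higher in Eif2s3y (7.99 and 7.82) than replicates 2 and 4 (6.47 and 6.45). Tesk1 lay at 6.6 and 9.54 on the former and at 6.59 and 6.77 on the latter. Rusc2 lay at 9.25 and 11.3 against 9.76 and 9.5, and Necap2 at 7.21 and 9.79 against 7.41 and 7.25. These genes thus did not follow Eif2s3y on chip 1. A shared source of the arrays in a set stays open too, since the split was found from these probes and their number cannot decide it.

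The second pattern is the difference between untreated knockout and wild type that changed with the chip in 530 genes. Compressed fold changes on chip 1 are argued against, because the amino acid and stress genes had a ratio of chip 1 to chips 2 and 3 of 0.916, where cell division and cholesterol synthesis genes had 0.0646. The background spread, inferred as larger on chip 1, is argued against as the cause, because with the spread from detection quantiles the median size of these differences was 1.17 of that reported (420 genes then differed, 380 of them the same). A linear effect of sex, alike in both genotypes, is argued against as the whole cause. With the Eif2s3y level as a covariate the median size of the difference went from 0.563 to 0.601, a ratio of 1.07. The count of genes went from 530 to 227 with that covariate while the sizes stayed. On untreated knockout arrays Eif2s3y itself changed with the chip, from 6.46 to 6.5 on chip 1 against 8.98 to 9.83 on the others. The slope of the covariate therefore came almost wholly from wild type, and an effect of sex in knockout alone stays open. A different share of dividing and non-neuronal cells stays open, with 7 of 7 such lists lower in knockout on chips 2 and 3 and 6 of 7 on chip 1, and an effect of the genotype that varies with the culture stays open as untested.

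The third pattern is the set of genes near Atf4 that differ between genotypes with and without HCA. Of the called neighbours 2.56%, 1 of 39, were called for HCA in wild type, but so were only 4.36% of the other called genes, so the bound set beforehand could not tell ATF4 targets from other genes. Among genes lower by 1.5-fold or more, 0 of 4 neighbours and 19 of 94 others were called (p = 1, Fisher's exact test), and Sun2, among those 4, rose on chips 2 and 3 alone. That they are ATF4 targets and that a difference is carried along in the chromosome region around the disrupted gene both stay open. The odds ratio over 100 tested genes on each side was 1.43 (p = 0.0536, Fisher's exact test), and with HCA it was 1.3 (p = 0.119). Over 5 genes on each side, 3 of 10 differed by 1.5-fold or more against 1.21% elsewhere (p = 0.000211, Fisher's exact test), a window chosen after the genes were seen.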

How the results depend on the processing

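The settings with a background spread from detection quantiles, the array sets as a block, the Eif2s3y covariate and 2 apart arrays left out were chosen after the data were seen. Arrays on chips 2 and 3 had a lower signal over background than those on chip 1, with mean signals from 296 to 669 against 745 to 983, which limits what can be said of dim genes there. Leaving single arrays out aside, 4102 values of named genes kept direction and side of the threshold, 831 lost the call, 5 gained it and 18 turned. For the lists the counts were 2156, 118, 80 and 21. Except where stated, the cause of a change was not tested.

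With median centring the counts were 16, 67, 2, 0 and 0, in the order untreated, HCA, HCA in wild type, HCA in knockout and difference between responses, and 165 and 253 genes passed at an unadjusted p in the last 2. The median of all genes then lay at 0.09, 0.36, -0.39, -0.10 and 0.28. Turned under HCA were Cdkn1a (0.09594), Gstp1 (0.01581), Mgst3 (0.1623), Dusp1 (0.04602), Hsph1 (0.05198), Dnajb1 (0.2808), Pgk1 (0.04008) and Tubb3 (0.1157), and for HCA in wild type Ddit3 (-0.02621), Cdkn1a (-0.02532) and Gars (-0.1239). With the background spread from detection quantiles and median centring, none of these genes turned, and the counts were 154, 412, 18, 1 and 19.

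Without a chip term the counts were 305 untreated, 848 with HCA and 34 for the difference between responses. On chips 2 and 3 only they were 1942 untreated, 254 for HCA in wild type and 42 for the difference between responses, and 1082, 120 and 33 genes were shared with the reported ones. There the list medians of cholesterol synthesis turned to -0.0714 (HCA in wild type), 0.0159 (HCA in knockout) and 0.0493 (difference between responses). The difference between responses turned to 0.277 for cell division and, relative to other genes, to -0.0238 for ER chaperones. With an estimated correlation it passed on these chips for cell division (adjusted p = 0.0316) and for microglia (median -0.309, adjusted p = 0.0201). Within chip 1, 31 genes differed untreated, and Hsph1 (0.0001039), Bag3 (0.1266), Pgk1 (1.617e-05), Slc17a6 (-0.061) and, relative to other genes, ER chaperones (-0.00138) turned. Within chip 2 the counts were 421, 610, 24, 0 and 3, and within chip 3 they were 753, 665, 19, 0 and 3, from fewer arrays, with 164 and 454 genes at an unadjusted p for the zeros. Within chip 2 cholesterol synthesis turned to -0.16 (HCA in wild type), progenitors, relative to other genes, to -0.016 (HCA in knockout), and the difference between responses to 0.173 for cell division, 0.0755 for cholesterol synthesis, 0.0145 for ER chaperones and, relative to other genes, -0.0134 for heat shock. Within chip 3 astrocytes turned to -0.108 (HCA in wild type), cholesterol synthesis to 0.0232 (HCA in knockout), and the difference between responses to 0.385 for cell division, 0.11 for ER chaperones and, relative to other genes, -0.0528 for cholesterol synthesis.

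With the replicate block in place of chip the counts were 797 untreated, 4347 for HCA in wild type, 4550 for HCA in knockout and 40 for the difference between responses. HCA replicates 1 to 4 share numbers with the controls of chip 1, so this block sets chip 1 against chips 2 and 3 and mixes chip with treatment. Under it Ier3 (-0.1157), Adra2c (0.08041), Scrn1 (0.09823), cholesterol synthesis (-0.0761) and microglia (-0.194) turned for HCA in wild type. As a random block with the chip term it moved none of the 5 counts by over 1.5 times. Of 28 pairs of arrays with the same number in different groups, 5 had a correlation above 0.1, with a range from -0.429 to 0.206. Only 1 array correlated best with its own number, so equal numbers were not taken to pair the samples. Other pairings were not looked at. On chips 2 and 3, runs of 4 places hold controls 5, 6, 7 and 8 of both genotypes beside HCA replicates 1, 2, 3 and 4. A pairing of those arrays was not tested, and the main fit has no term for it.

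For HCA in knockout the count was 3 with no detection filter, 2 with probes detected on all arrays and 0 with only the groups compared, where 429 genes passed at an unadjusted p in limma. With only the groups compared, cholesterol synthesis turned to -0.0714 (HCA in wild type) and 0.0159 (HCA in knockout). With wild-type control replicate 2 and wild-type HCA replicate 1, the arrays that stand apart for most probes, left out together, the counts were 88 for HCA in wild type and 47 for the difference between responses.

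Leaving out each array in turn, the count ranged from 868 to 1449 untreated, from 1473 to 2040 with HCA, from 74 (without wild-type HCA replicate 1) to 176 for HCA in wild type, from 0 to 9 for HCA in knockout and from 47 to 79 for the difference between responses. For HCA in knockout it was 0 without knockout HCA replicate 3, knockout HCA replicate 4 or knockout control replicate 7 (566, 645 and 823 genes at an unadjusted p in limma), 9 without knockout control replicate 3, 2 without knockout control replicate 5 and 3 without any of wild-type controls 1, 5 and 7, knockout controls 1, 2, 4 and 6, wild-type HCA replicates 2, 3 and 4 or knockout HCA replicate 2. The count for the difference between responses was 47 without wild-type HCA replicate 1 or knockout HCA replicate 4, 49 without knockout HCA replicate 3 and 50 without wild-type HCA replicate 4.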

Other observations

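On chips 2 and 3 alone, more lists differed between untreated knockout and wild type. Of 15 cell division genes 13 were lower in knockout (median -0.97), of 14 cholesterol synthesis genes 12 (median -0.78) and of 11 ER chaperone genes 9 (median -0.53), and these lists passed with an estimated correlation there (adjusted p = 0.00484, 0.00484 and 0.00522). Markers of some other cells fell with them and passed too. Lower were 7 of 10 progenitor genes (median -0.52), 4 of 5 genes of meninges and fibroblasts (median -0.64) and 5 of 8 inhibitory neuron genes (median -0.35). Their adjusted p was 0.0197, 0.0256 and 0.0414. Of 12 glutathione genes 8 were lower as well (median -0.31, adjusted p = 0.00301). The lists of astrocytes, microglia, endothelium and the oligodendrocyte lineage did not pass with an estimated correlation (adjusted p = 0.129, 0.129, 0.223 and 0.0843). With HCA in wild type, 7 of 15 cell division genes fell on these chips (median -0.30, adjusted p = 0.0124 with an estimated correlation). Progenitor genes shifted down with them (median -0.27, adjusted p = 0.0258) and microglia genes shifted up (median 0.23, adjusted p = 0.0277).

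The 92 genes that rose with HCA in wild type over all arrays had a median response of -0.02 in knockout on chips 2 and 3. There 39 were positive and 0 were called higher (limma). Over all tested genes and all arrays, 737 genes of either direction passed at an unadjusted p for HCA in knockout. The 54 genes that fell in wild type had a median of -0.11 in knockout, where 9 were positive. Of the 25 genes lower in knockout on chip 1, 10 were not called for HCA in wild type, which does not show that they lack a response. Among them, Mcat (-1.07), which lies 31 tested genes from Atf4, and Tgfbi (-1.04), a matrix protein gene, had adjusted p = 0.372 and 0.413. They differed by -1.13 and -1.28 between the genotypes on chips 2 and 3.

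No 2 arrays held identical signals. The highest correlation of log2 signals between arrays was 0.9948, and the lowest SD of the log2 difference between arrays of a group was 0.147, against a median of 0.227 within a chip. The first principal component held 49.2% of the variance and separated chip 1 from chips 2 and 3, and the second held 17.6%.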
